A study of Mus musculus with 3 samples.

How the data were processed

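RNA from mouse brain was measured in 3 libraries. Per the labels, each came from the middle section of a brain hemisphere taken after 3 days. The occluded animals had middle cerebral artery occlusion (MCAO, a blocked brain artery used as a stroke model) for 1 h. Ribosome-bound RNA was isolated by a RiboTag pull-down, in which an epitope-tagged ribosomal protein carried by chosen cells is precipitated together with the transcripts being translated. The series title speaks of astrocytes, and the labels name no driver line. The series design states that each library pooled 3 animals, with 2 technical replicates, and that RNA from repeated pull-downs was combined. The labels name a TruSeq RNA sample preparation kit for the libraries.

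The table used here holds gene symbols and 1 column per library, and its values are a signal, namely read counts divided by a size factor per library, deposited by the authors in that normalised form. The submitters' processing notes name CASAVA 1.8, HISAT2 2.0.11, Partek 6.6, R 3.3.1 and the genome build mm10, without giving each one's role. The authors' notes also name DESeq2, with no version. The table listed 16610 genes. The highest of the 3 values of every gene was 10.6 or more, and values below 1 were listed as 1. No statement on strand was found in the sources used here, so reads of overlapping or antisense genes may be mixed. Members of near-identical families, such as Lilrb4a and Lilr4b or the MHC and haemoglobin genes, can share reads and their single values are uncertain.

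Whole reads were recovered by finding what 1 read is worth in each column. It was worth 0.969 normalised counts in the no-MCAO right hemisphere, 0.887 in the right hemisphere of the MCAO animals and 1.18 in the left MCAO hemisphere. In each column 99.9% of the values above 1 were whole within 0.1 read. The recovered totals were 31833456, 33886604 and 25930258 reads in the same order.

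Columns were matched to libraries through the sample descriptions, and no column of values was left unused. Each group had 1 library, so every difference has no replicate check and no p-value was computed. Differences were taken on the log2(value + 5) scale, which understates differences of low genes, for 14906 genes with a mean of at least 20 over the 3 libraries. A gene was counted for the MCAO hemisphere where it was at least 2-fold higher, or lower, than in both right hemispheres. The right hemisphere of the MCAO animals was compared with the no-MCAO right hemisphere at the same size. Ratios printed as folds are ratios of the normalised counts without the pseudocount. Their 95% intervals are exact Clopper-Pearson intervals from the recovered reads, and cover counting error only, since reads without molecular identifiers are not independent molecules. A value listed at 1 stood for 0 reads in the MCAO hemisphere library and for 0 or 1 read in the other libraries, where 1 read was worth less than 1. Intervals took 1 read there. For a ratio to a value listed at 1, the lower end of that interval is given. The median of the male germ cell list was also taken with such values raised to that of 3 reads.

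For 38 gene lists fixed before the data were examined, the median log2 difference over members past the filter was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The resulting percentile describes these libraries and is not a test. Lists with fewer than 3 such members have no percentile. A further 9 lists of testis cells and other organs were written after the values were seen. The lists overlap in part, for example those of reactive astrocytes and of chemokines.

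Named genes were chosen by a rule set before the data were examined. They are the 15 highest and 10 lowest genes of the MCAO hemisphere by the smaller of both differences, and the 6 highest and 6 lowest of the contralateral comparison. Up to 4 members with the largest differences were added per list described, together with Gfap, Vim, Lcn2, Serpina3n, Stat3, C3, Aqp4, Slc1a2, Slc1a3, Aldh1l1 and Glul. Predicted genes and small RNA hosts were skipped, and some members of the lists are not reported here. Genes named outside this rule are marked in the text as chosen after their values were seen. Gene coordinates were taken from a RefSeq gene table for GRCm38.p6, the assembly called mm10, in which 15912 of the 16610 symbols were found.

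The counting procedure was tested on simulated reads drawn for the comparison of the MCAO hemisphere with both right hemispheres, over 14906 genes. Of 50 genes set 4-fold higher 100% were recovered, and of 50 set 4-fold lower 98%. At 8-fold the shares were 100% and 98%, and 3 unchanged genes were counted beside the 200 changed ones. In 20 simulated sets with no difference between the libraries, the highest counts were 1 gene higher and 3 lower in the MCAO hemisphere, and 4 higher and 3 lower in the contralateral comparison. These sets hold counting error and no variation between animals.

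Other pseudocounts, filters, sizes of difference, scalings and reference libraries were planned as alternatives. A test of the recovered reads, requiring the 95% interval of each ratio to exclude no difference, and a count without genes at 3 reads or fewer in both the no-MCAO and the MCAO hemisphere libraries were added after the data were seen. The test of reads compares libraries and not conditions. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.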

Results

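Transcripts bound to tagged ribosomes were sequenced from 3 pools of mouse brain hemispheres, with 1 library per group and 3 animals per pool. The groups were the right hemisphere of animals without occlusion (control), the right hemisphere of animals with MCAO (contralateral) and the left hemisphere of animals with MCAO (MCAO hemisphere). The recovered depth was 31833456, 33886604 and 25930258 reads. In the control, the median normalised read count was 14035 over 26 astrocyte identity genes, 13310 over 19 neuron genes, 407 over 20 microglia genes and 91.5 over 14 endothelial genes. The medians of the neuron and astrocyte lists were thus close in this library, which does not measure the share of transcripts from each cell type. Intervals of ratios are 95% counting intervals, and no difference has a replicate check. Left and right cannot be separated from occlusion, since the labels give no left hemisphere without MCAO.

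The first comparison asked which ribosome-bound transcripts differed in the hemisphere with the occlusion. Genes of reactive astrocytes, cell division and myeloid cells were higher in the MCAO hemisphere, and genes of striatal neurons were lower. Gfap, the intermediate filament protein used as a marker of reactive astrocytes (chromosome 11, 102887336 to 102897200), had 5903 normalised counts in the control, 12202 in the contralateral library and 76049 in the MCAO hemisphere. This was 12.9-fold the control (12.5 to 13.2) and 6.23-fold the contralateral value (6.12 to 6.35). Vim, encoding vimentin (chromosome 2, 13574311 to 13582826), had 707, 1351 and 14359 normalised counts in the same order, a 20.3-fold difference from the control (18.8 to 21.9). Lcn2, encoding the secreted iron-siderophore binder lipocalin 2 (chromosome 2, 32384637 to 32387739), had 10.7, 54.1 and 981, a 92.1-fold difference (51.2 to 185).

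In all, 384 genes were at least 2-fold higher in the MCAO hemisphere than in both right hemispheres and 77 were at least 2-fold lower. Both comparisons share the MCAO library. Independent lists of the same sizes would share 19.5 and 9.28 genes, and simulated unchanged libraries gave at most 1 and 3. Set against the control alone, the counts were 614 and 187.

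The gene with the largest difference was Tgm1, a transglutaminase that cross-links proteins (chromosome 14, 55700009 to 55713921). It had 2.91, 13.3 and 1870 normalised counts, which was 644-fold the control (220 to 3125) and 141-fold the contralateral value (84.9 to 252). Msr1, a macrophage scavenger receptor, had 4.84, 5.32 and 519, and the interferon-inducible gene Ifi202b had 1.94, 3.55 and 311. Lgals3, encoding galectin-3 (chromosome 14, 47373860 to 47386167), had 32.0, 42.6 and 1628, a 50.9-fold difference from the control (36.1 to 74.3). Spp1, encoding osteopontin (chromosome 5, 104435111 to 104441053), had 251, 487 and 8736, a 34.8-fold difference (30.8 to 39.6). The protease inhibitor gene Timp1 had 2.91, 19.5 and 428 normalised counts, and the protease gene St14 had 274, 270 and 3445. The metalloprotease gene Adam8 had 8.72, 7.99 and 295, and Ctse, encoding the aspartic protease cathepsin E, had 16.5, 12.4 and 273. The immune receptor genes Lilrb4a and Cd72 had 355 and 253 normalised counts in the MCAO hemisphere, against 2.91 and 9.69 in the control. The chemokine gene Cxcl13 had 193 against 2.91, and the cytokine gene Clcf1 had 262 against 11.6. Lilr4b, a close relative of Lilrb4a, was listed at the minimum of 1 in both right hemispheres and had 72.9 normalised counts in the MCAO hemisphere, and the 95% interval of its ratio to the control, taking 1 control read, began at 13.

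**Figure D1:**
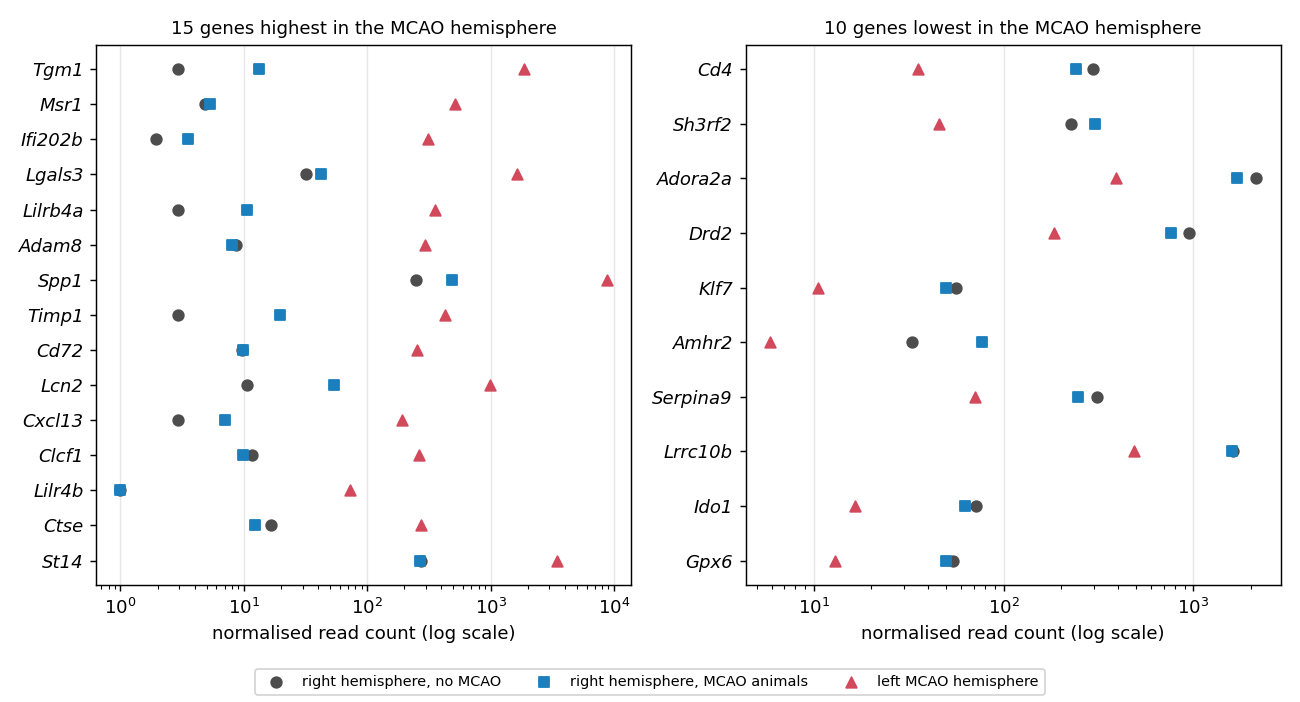
Normalised read counts on a log axis in the 3 libraries (1 pooled library per point) for the 15 genes with the largest and the 10 with the most negative difference in the MCAO hemisphere. Tgm1 stood at 1870 in the MCAO hemisphere against 2.91 in the control, and Cd4 at 35.3 against 297; values of 1 are the listed minimum.

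Reactive astrocyte lists stood apart from random lists in the MCAO hemisphere. Of 12 pan-reactive genes past the filter, 11 were at least 2-fold higher than in both right hemispheres, and the median log2 difference from the control was 3.02, above all 10000 random lists. Of 11 genes associated with the A2 state, described for ischaemia, 9 were higher, with a median of 2.55, again above all random lists. Emp1 had 73.6, 79.9 and 579 normalised counts, and Cd14, a co-receptor for bacterial lipopolysaccharide, had 49.4, 61.2 and 438. Cd14 also belongs to the macrophage and activated myeloid list. Myeloid markers were higher in this library too, and the cells that gave the transcripts of the reactive lists were not identified. Of 11 genes associated with the A1 state, described for inflammation, 4 were higher, with a median of 0.80, which also lay above all random lists. Against the contralateral library the medians of the pan-reactive, A2 and A1 lists were 2.65, 1.78 and 0.89. The higher A1 genes included Srgn, with 49.4, 57.7 and 229, and the immunoproteasome gene Psmb8, with 115, 99.4 and 294. C3, the complement component often used as an A1 marker, had 49.4, 32.8 and 74.1 normalised counts, which was 1.5-fold the control (1.02 to 2.21). Serpina3n had 6171, 8471 and 25376, a 4.11-fold difference from the control (4.0 to 4.23).

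None of the 26 astrocyte identity genes differed 2-fold from either right hemisphere, and their median log2 difference from the control was 0.05, at the 96.3rd percentile of random lists. The water channel gene Aqp4 had 8837, 8912 and 11018 normalised counts, and Aldh1l1, a folate enzyme used as an astrocyte marker, had 6381, 5967 and 8750. The glutamate transporter genes Slc1a2 and Slc1a3 were lower in the MCAO hemisphere, at 0.749-fold (0.743 to 0.755) and 0.695-fold (0.685 to 0.705) of the control. Glul, encoding glutamine synthetase, was at 0.95-fold (0.942 to 0.958). Against the contralateral library Slc1a2 was at 0.931-fold (0.923 to 0.939), Slc1a3 at 0.753-fold (0.743 to 0.764) and Glul at 0.796-fold (0.789 to 0.802). The list of 17 glutamate, GABA and ion transport genes had a median of -0.07 against the control, at percentile 45.0, and of -0.10 against the contralateral library, at percentile 0.36.

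Cell cycle genes were higher in the MCAO hemisphere. Of 20 past the filter, 18 were at least 2-fold higher than in the control and 13 higher than in both right hemispheres, with median log2 differences of 2.51 from the control and 1.31 from the contralateral library, both above all random lists. The proliferation marker Mki67 had 33.9, 58.6 and 395 normalised counts, Cdk1, the kinase that drives mitosis, had 22.3, 34.6 and 251, and the ribonucleotide reductase gene Rrm2 had 52.3, 67.4 and 400. The neural progenitor list had 2 of 15 genes higher than in both, with medians of 0.47 against the control and -0.06 against the contralateral library. These were Nes, encoding the filament protein nestin, with 163, 232 and 2182, and the lipid-binding protein gene Fabp7, with 2547, 3357 and 7013.

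The JAK-STAT3, interferon-stimulated, chemokine and cytokine, complement and MHC class I lists had medians above the central 95% of random lists against both right hemispheres. In the JAK-STAT3 list 4 of 14 genes were higher than in both, with a median of 0.70 against the control. The feedback inhibitor gene Socs3 had 77.5, 81.6 and 422 normalised counts and the oncostatin M receptor gene Osmr had 34.9, 48.8 and 272. Stat3 itself had 1646, 2140 and 3382, a 2.05-fold difference from the control (1.93 to 2.18). In the interferon-stimulated list 8 of 17 genes were higher than in both, with a median of 1.49, among them Usp18 at 12.6, 13.3 and 89.4 and Ifi44 at 13.6, 24.8 and 125. In the chemokine and cytokine list 8 of 14 were higher, with a median of 1.21. Ccl4 was listed at 1 in both right hemispheres and had 65.9 normalised counts in the MCAO hemisphere, and Cxcl10 had 5.81, 10.6 and 95.3. In the complement list 3 of 10 were higher, including C4b at 1525, 2254 and 6686. The MHC class I list had a median of 0.84, above all random lists, with 1 of 12 genes higher than in both, and the MHC class II list of 6 had a median of 0.47, at percentile 92.9 and inside that central range.

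In the extracellular matrix and scar list 6 of 22 genes were higher than in both, among them fibronectin gene Fn1 at 115, 171 and 1217 normalised counts and the hyaluronan receptor gene Cd44 at 130, 130 and 1016. The median of that list was 0.16 against the control, at percentile 97.6, and 0.30 against the contralateral library. In the matrix protease and inhibitor list 8 of 19 were higher, with a median of 0.82.

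Markers of microglia and myeloid cells were higher in the same library. Of 20 microglia genes, 13 were at least 2-fold higher than in both right hemispheres, with a median of 1.28 against the control, and of 10 macrophage and activated myeloid genes 7 were, with a median of 2.59. Both medians lay above all random lists, and against the contralateral library they were 1.45 and 2.21. The microglial receptor gene Trem2 had 124, 143 and 822 normalised counts, the complement gene C1qa had 664, 667 and 3169, and Gpnmb, a glycoprotein of activated phagocytes, had 58.1, 63.9 and 471. The other 7 microglia genes were within 2-fold of the control. Among them, chosen after their values were seen, P2ry12 had 405, 382 and 418 and Tmem119 had 475, 403 and 587. Of 2 neutrophil genes past the filter, Csf3r was higher, at 81.4, 96.7 and 314. None of the 19 neuron, 13 oligodendrocyte, 13 endothelial or 10 mural genes differed 2-fold from the control, and their medians were -0.19, 0.24, 0.17 and -0.05, at percentiles 3.24, 99.8, 72.7 and 29.3. Against the contralateral library 2 endothelial genes were at least 2-fold higher, and the 4 medians were 0.00, 0.29, 0.31 and 0.34, at percentiles 49.8, 100, 97.2 and 99.6. Of 10 oligodendrocyte precursor genes 2 were at least 2-fold higher than in the control, with a median of 0.06, and the median against the contralateral library was 0.27, at percentile 99.9.

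**Figure D2:**
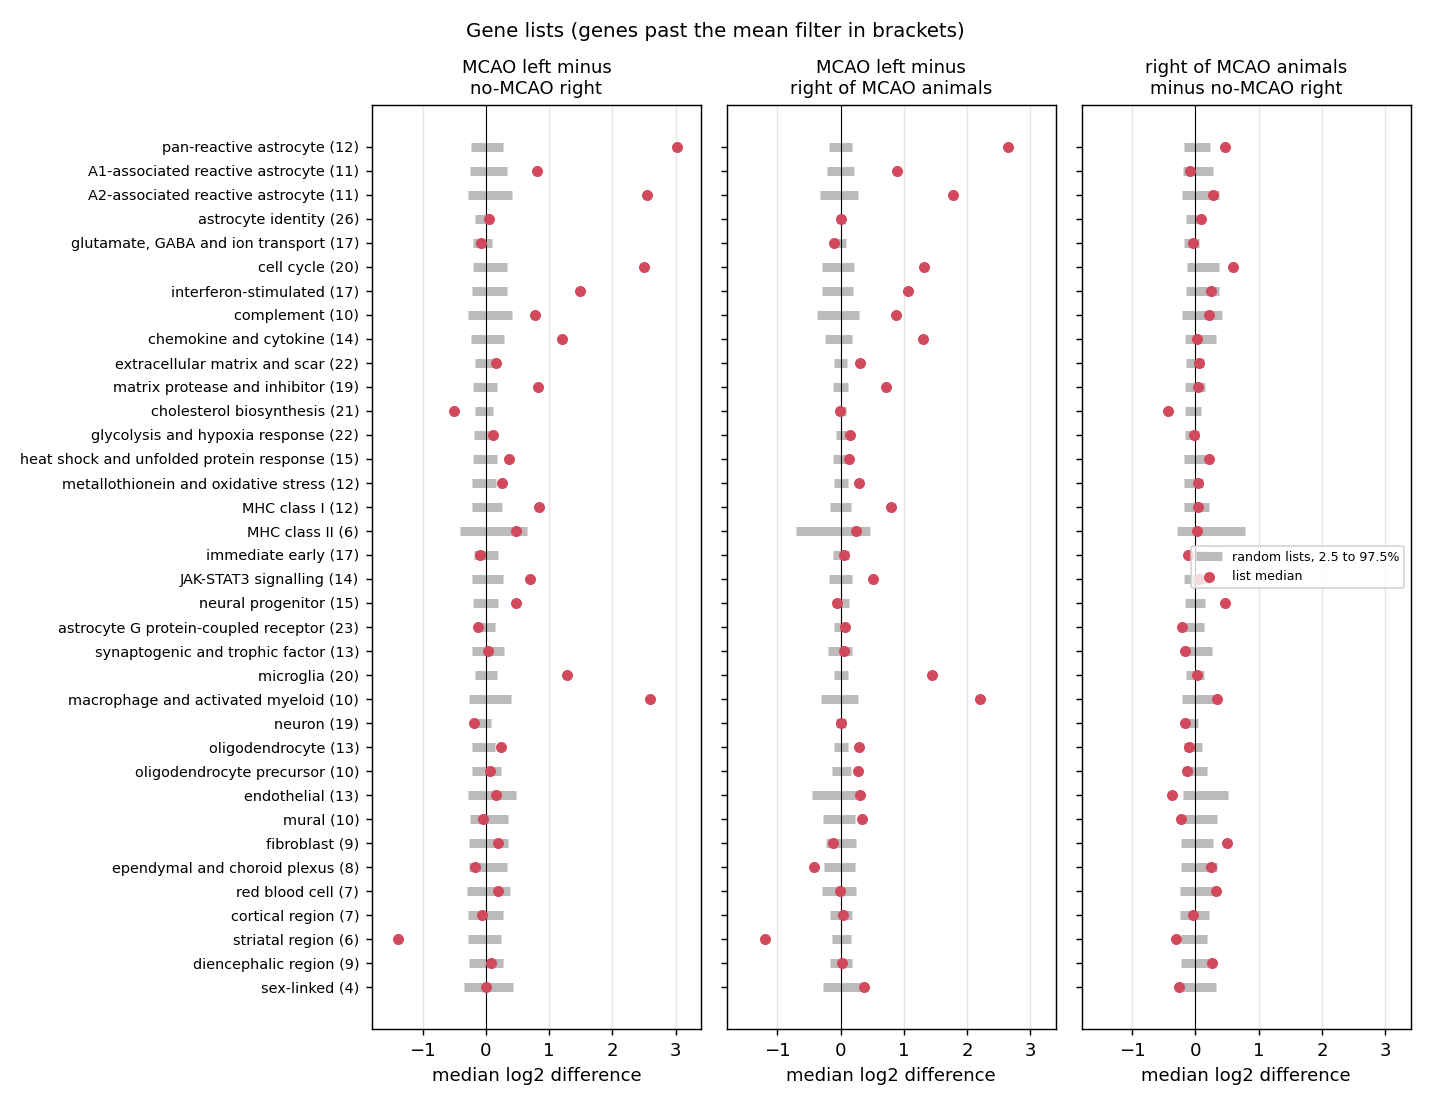
Median log2 difference of each gene list with at least 3 genes past the mean filter, in the 3 pairs of libraries. Grey bars span the central 95% of 10000 random lists matched on mean expression; the pan-reactive astrocyte list stood at 3.02 and the striatal region list at -1.39 in the MCAO hemisphere against the control.

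Genes of striatal medium spiny neurons were lower in the MCAO hemisphere. Of 6 striatal genes 5 were at least 2-fold lower than in the control and 4 lower than in both right hemispheres, and the median of -1.39 lay below all random lists. Drd2, the D2 dopamine receptor gene (chromosome 9, 49340360 to 49408177), had 951, 761 and 185 normalised counts and was 5.15-fold lower than in the control (4.35 to 6.13). Adora2a, an adenosine receptor gene (chromosome 10, 75316877 to 75334792), had 2140, 1694 and 389 and was 5.5-fold lower (4.90 to 6.19). The dopamine signalling gene Ppp1r1b had 8270, 8395 and 3528. The 7 cortical genes had a median of -0.06 and 9 diencephalic genes a median of 0.08.

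Cd4, the only lymphocyte list member past the filter, had the most negative difference, with 297, 241 and 35.3 normalised counts. It was 8.43-fold lower than in the control (5.78 to 12.7). Sh3rf2 had 227, 303 and 45.9, Serpina9 had 312, 247 and 70.6, and Lrrc10b had 1607, 1589 and 487. Klf7 had 56.2, 49.7 and 10.6, Ido1, encoding a tryptophan-degrading enzyme, had 71.7, 63.0 and 16.5, Gpx6 had 54.2, 49.7 and 12.9, and Amhr2 had 32.9, 77.2 and 5.88.

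The second comparison set the contralateral right hemisphere against the control right hemisphere, and asked whether the side opposite the occlusion differed. The highest differences belonged to genes of sperm formation. Prm2, encoding a protamine that packs sperm DNA (chromosome 16, 10791377 to 10792105), had 5.81 normalised counts in the control, 1647 in the contralateral library and 2.35 in the MCAO hemisphere. This was 283-fold the control (130 to 773). Crisp2, encoding a sperm protein (chromosome 17, 40764734 to 40794146), was listed at 1 in the control and had 1132 normalised counts in the contralateral library, and the 95% interval of the ratio, taking 1 control read, began at 209. The transition protein gene Tnp1 was 371-fold the control (127 to 1803), the sperm lactate dehydrogenase gene Ldhc 207-fold (105 to 481) and the sperm tail gene Akap4 174-fold (88.3 to 405), and the interval of Tnp2, listed at 1 in the control, began at 133.

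Of the 14906 genes, 771 were at least 2-fold higher in the contralateral library than in the control and 54 were lower. Simulated unchanged libraries gave at most 4 and 3. Of the 771, 616 (79.9%) were also at least 2-fold above the MCAO hemisphere, against 38.3 for independent lists. The contralateral library is shared by both of these comparisons, and simulated unchanged libraries gave at most 1. Of the 54 lower genes, 16 were also at least 2-fold below the MCAO hemisphere. A further property of the contralateral library was that 701 genes had 3 reads or fewer in both other libraries. Such genes numbered 41 for the MCAO hemisphere and 11 for the control. The 701 genes held 0.160% of the contralateral total. Without genes of this kind, a count added after the data were seen, 542 genes were higher. These 542 still held sperm genes such as Prm2, Ldhc and Akap4, which had 6, 8 and 8 reads in the control.

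Genes of the pan-reactive astrocyte list were mostly higher in the contralateral library than in the control, by less than in the MCAO hemisphere. Of 12 pan-reactive genes 3 were at least 2-fold higher, and the median of 0.46 lay at the 99.97th percentile. The 26 astrocyte identity genes had a median of 0.10, at percentile 99.94, with none 2-fold higher. The striatal list had a median of -0.31 (percentile 0.16), the diencephalic list 0.27 (percentile 99.1), the astrocyte receptor list -0.22 (percentile 0.11), the heat shock list 0.22 (percentile 99.3) and the mural list -0.23 (percentile 1.32). Gfap was 2.07-fold the control (2.01 to 2.13), Vim 1.91-fold (1.75 to 2.09), Lcn2 5.08-fold (2.65 to 10.7) and Serpina3n 1.37-fold (1.33 to 1.42). The A2 list had a median of 0.28 (percentile 92.3) and the A1 list a median of -0.09 (percentile 16.8). Microglia genes had a median of 0.03 (percentile 71.2), and 2 of 20 were at least 2-fold higher, Aif1 at 79.4 and 259 normalised counts and Tyrobp at 92.0 and 204. Of 20 cell cycle genes 7 were at least 2-fold higher, with a median of 0.60. The spindle checkpoint gene Bub1 had 1.94, 63.9 and 47.1 normalised counts in the control, contralateral and MCAO libraries, and Cenpf had 14.5, 148 and 167. Male germ cell genes were higher in this same library, by a median of 5.53 over 18 genes, in a list written after the values were seen. With the control value of 5 genes listed at 1 raised to that of 3 reads, on the same log2 scale, the median was 5.43. Whether the higher microglia and cell cycle genes shared a source with these germ cell genes was not tested. The neural progenitor list had a median of 0.47, above all random lists, with 1 of 15 genes, the Notch target Hes5, at least 2-fold higher (486 and 1291 normalised counts).

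**Figure D3:**
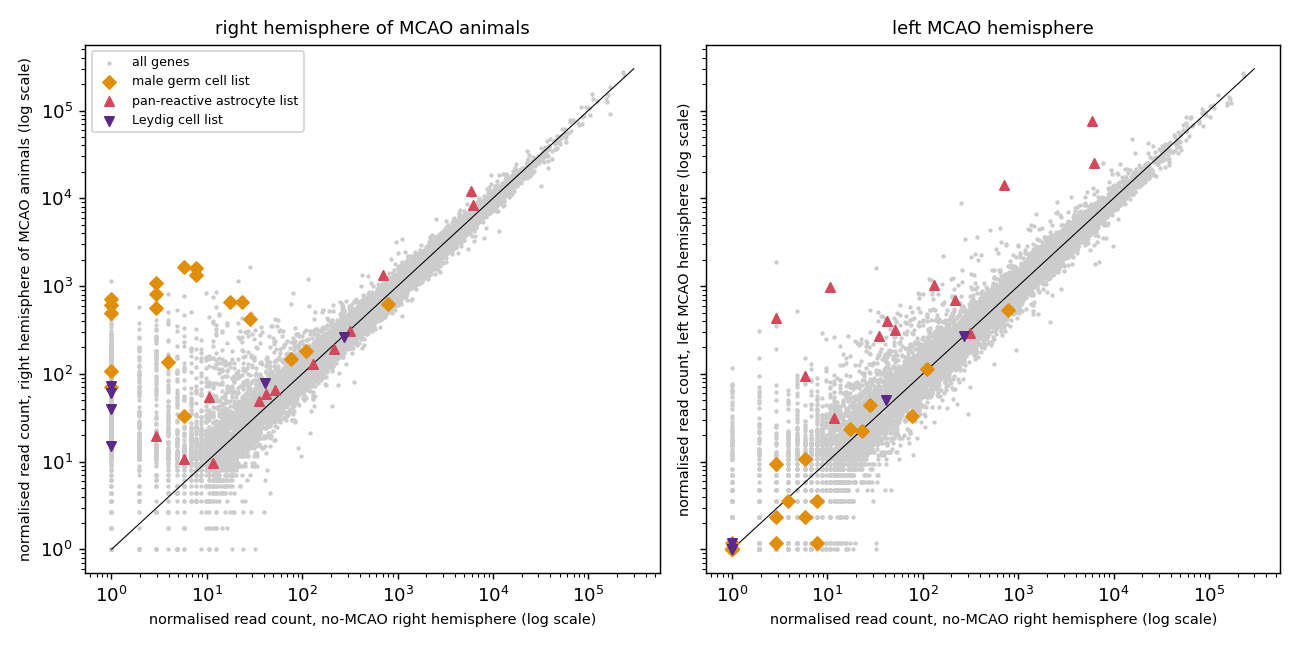
Normalised read counts of all genes in the control right hemisphere against the contralateral library and against the MCAO hemisphere, both axes on a log scale, with the line of equal values. Male germ cell genes stood above the line in the contralateral library (Prm2 at 1647 against 5.81), and pan-reactive astrocyte genes in the MCAO hemisphere (Gfap at 76049 against 5903).

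The lowest differences in the contralateral library belonged to Eomes, a transcription factor of cortical progenitors and olfactory bulb neurons, with 96.9 normalised counts in the control and 11.5 in the contralateral library, which was 8.4-fold lower (4.69 to 16.3). Doc2g had 207 and 43.5, Chn1os3 had 42.6 and 7.99, and Zfp382 had 346 and 79.9. Adnp had 238 and 75.4, and Prss56 had 125 and 38.2. In the MCAO hemisphere Eomes had 28.2, Doc2g 51.8, Chn1os3 15.3, Zfp382 232, Adnp 120 and Prss56 42.3. All of these were below the control there too. Both comparisons share the control library, so a property of that pool would move both. The 13 endothelial genes had a median of -0.36, at percentile 0.03, with none 2-fold lower, and 9 fibroblast genes had a median of 0.51, at percentile 99.95, with none 2-fold higher.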

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

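The 4 counts were 384 genes higher and 77 lower in the MCAO hemisphere than in both right hemispheres, and 771 higher and 54 lower in the contralateral library than in the control. Under a pseudocount of 1, 132 genes were lower in the MCAO hemisphere. Under a pseudocount of 20, 28 were lower there and 27 lower in the contralateral library. With no filter on the mean, 1415 were higher and 112 lower in the contralateral library. With a mean of at least 100 the 4 counts were 199, 30, 188 and 16, where fewer genes were counted. At 1.5-fold they were 727, 331, 1256 and 336, and at 4-fold 123, 4, 501 and 5, by construction of the size. Against the control alone the MCAO counts were 614 and 187, and against the contralateral library alone 740 were lower, the latter including genes that were high in the contralateral library. The causes of the other shifts were not tested. The 4 genes at least 4-fold lower in the MCAO hemisphere were Cd4, Sh3rf2, Adora2a and Drd2. The 5 in the contralateral library were Eomes, Doc2g and Zfp382 with the predicted genes Gm28042 and 1500017E21Rik, which were named after their values were seen. Equal totals, medians of ratios and upper quartiles gave counts within 1.5 times the main ones. In the test of reads, added after the data were seen, 384, 71, 769 and 54 genes passed. It was applied only to the genes already counted, so it could only lower the 4 counts. Over the alternative settings, 108 list medians and 93 differences of named genes were recomputed, which gave 1329 values. Of these values 0 reversed and 113 moved beyond their counting interval, 38 of them gene differences under a pseudocount of 20. A value could be called reversed only where the counting interval of the main value excluded 0. No paired analysis was possible because each group had 1 library, and no library could be left out within a group. Genes near 3 reads had intervals spanning several fold, so depth limits their ratios.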

Other observations

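All tests of explanations below were chosen after the results were seen, and so were the lists of testis cells and other organs and the genes Pmvk, Ebp, Meg3, Rn45s, S100a5, P2ry12, Tmem119 and Camk2a.

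Of 21 cholesterol biosynthesis genes, 19 had lower values in both hemispheres of the MCAO animals than in the control, and 2, Pmvk and Ebp, had higher values in both. The list had a median log2 difference of -0.50 in the MCAO hemisphere and -0.44 in the contralateral library, both below all 10000 random lists, and of -0.00 between those hemispheres. Sc5d, which acts late in the pathway, had 1350 normalised counts in the control, 918 in the contralateral library and 793 in the MCAO hemisphere. None of the 21 differed 2-fold, and both differences share the same control library, so a property of that pool would move both. Metallothionein and oxidative stress genes had a median of 0.25 in the MCAO hemisphere against the control, with Hmox1, encoding heme oxygenase 1, at 220, 331 and 693 and Mt2 at 5286, 8726 and 11826. The heat shock list had a median of 0.36, with the small heat shock protein gene Hspb1 at 41.6, 59.4 and 400 and the stress transcription factor Atf3 at 29.1, 15.1 and 126. The glycolysis and hypoxia list had a median of 0.11, with Hk2 at 133, 172 and 301. Immediate early genes had a median of -0.09, the synaptogenic and trophic factor list 0.04 and the astrocyte receptor list -0.12, within which the sphingosine 1-phosphate receptor gene S1pr3 had 218, 190 and 699. Fibroblast, ependymal and red blood cell lists had medians of 0.19, -0.17 and 0.20 against the control, and the ependymal list had -0.42 against the contralateral library, at percentile 0.29. The Y-linked genes of the sex-linked list were read in all 3 pools, with a median of -0.00 over 4 genes.

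The long noncoding RNA Meg3 had 11682, 4220 and 10251 normalised counts in the control, contralateral and MCAO libraries, and the ribosomal precursor Rn45s had 31857, 13797 and 27300. Noncoding RNAs were not examined as a group. S100a5, a gene of olfactory neurons, had 18.4 normalised counts in the control and was listed at the minimum of 1 in the other libraries. Neuronal Camk2a had 102988, 89034 and 84031 normalised counts.

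Male germ cell genes in the contralateral library are a pattern with a candidate source, RNA or reads from testis. With no filter on the mean, 16 of 20 such genes were at least 2-fold higher than in the control, where 5 of the 18 past the filter had 20 normalised counts or more. Leydig cells share the organ but not the lineage. Of their 7 genes 4 were higher, among them Insl3 (60.3 against the listed minimum of 1) and Cyp17a1 (73.6 against 1). So were 1 of 8 Sertoli cell genes and 0 of 51 genes of liver, muscle, kidney, pancreas, ovary and skin. Many of these had no listed value and could not be counted as higher. Values were listed for 3 of 8 Sertoli, 2 of 10 liver and 7 of 10 muscle genes. For kidney, pancreas, ovary and skin they were listed for 2 of 8, 2 of 8, 1 of 8 and 3 of 7. The contrast with other organs rests on the listed genes alone. Genes of both testis lineages were higher, which RNA or reads from testis would give. In the MCAO hemisphere, 0 of the 18 germ cell genes past the filter were at least 2-fold higher than in the control and 2 were lower. Their median log2 difference there was -0.02, so a response to the occlusion would have to be limited to the contralateral side. Such a response stays open with 1 contralateral pool. Testis reads could have entered as RNA, cDNA or misassigned reads, which was not tested.

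Pan-reactive astrocyte genes higher in the contralateral library are the second pattern, with a list median at percentile 99.97. The 11 of its 12 genes that were at least 2-fold higher in the MCAO hemisphere than in the control gained a median of 4.45% of their MCAO value (95% bootstrap interval over genes 3.88 to 5.13), from -4.01% for S1pr3 and -0.02% for Cd44 to 9.06% for Serpina3n, and 63 genes outside the list, at least 8-fold higher there, gained a median of 3.77% (2.43 to 5.73 over genes). One uniform share of that library is argued against by Tgm1, whose contralateral value was at most 1.57% of its MCAO value, an upper limit corrected for 74 genes, and by Msr1, at most 3.35%; this limit was taken up after the medians had been compared. A share from tissue of another composition, such as the border of the lesion, was not tested. Testis reads stay open too, since no testis profile was used here (Gfap gained 6299 normalised counts, 3.84 times the gain of Prm2), and a response of the contralateral hemisphere cannot be told apart from these with 1 pool.

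Microglia markers higher in the MCAO hemisphere are the third pattern, in libraries meant to hold astrocyte ribosomes. A less pure pull-down would raise the markers of other cell types alike only if the background RNA kept its composition, which was not tested. Against the control, the microglia median exceeded that of oligodendrocytes by 1.04 (95% bootstrap interval over genes 0.39 to 1.72). Oligodendrocytes had the highest median of 5 other cell types, itself at percentile 99.8. If the composition was kept, this gap argues against a general loss of purity as the whole cause. Against the contralateral library the microglia median was 1.45. Oligodendrocyte, precursor, endothelial and mural medians were 0.29, 0.27, 0.31 and 0.34 there, at percentiles 97.2 to 100, and the neuron median 0.00. More microglial RNA in the tissue that the pull-down started from stays open because input RNA was not analysed here. Of 20 microglia genes 13 were at least 2-fold higher. The rise was not uniform, with the other 7 within 2-fold of the control, among them P2ry12 (405 and 418) and Tmem119 (475 and 587). These values cannot decide on the amount of microglial RNA, since amount and expression within microglia were not separated. Expression of the microglia genes by tagged cells was not tested.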
